A study of Rattus norvegicus with 24 samples.

How the data were processed

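Thyroid glands of RccHan Wistar rat pups were profiled on 24 rat Agilent 1-colour arrays, 1 sample per array, in 6 groups of 4. Per the labels, dams were dosed with acrylamide in drinking water at 3 mg per kg body weight per day from gestational day 6, and the pups stayed on that dose until postnatal day 35 ± 3, while controls drank tap water. Glands were collected at 10 PM from females and males and at 10 AM from females. Arrays from males in the morning and plasma hormone levels were not analysed here. The labels describe 5 male and 5 female pups killed at each time but do not tie a replicate number to an animal, so p-values measure the spread between these samples. In a check of whether the replicate numbers pair the arrays, most arrays did not match best with the array of their own number. Over genes, deviations from the group means correlated at -0.229 to 0.355 between arrays of the same number. This gave no clear sign of pairing but cannot exclude it, and no pairing was used.

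Per the file headers, Agilent Feature Extraction 10.1.1.1 wrote for each spot a processed signal, which is an intensity on a linear scale after background and spatial trends had been removed within the array, together with raw intensity values for spot and local background and 0 or 1 flags for spots well above background, saturated or uneven. The deposited series matrix holds log2 values with a single value for each probe, and set against the scanner files each column followed log2 of the processed signal of its array minus a constant, so that each column's median was 0. The file headers name the rn4 build of the rat genome, and the probe positions given are on that build. Night arrays were read in scan session 1 with 0 saturated spots, and morning arrays in session 2 with 188 to 469 saturated spots per array. The saturation value was 7.79e+05 on night arrays and 65496 to 65497 on morning arrays. Bright spots therefore reached their limit at a lower signal in the morning. The 4 slides divide in the same way, with females at night on 1 slide, males at night on another and females in the morning on the remaining 2. Collection time in females is therefore confounded with slide and scan session, and sex at night with slide. On both night slides the controls lie in row 1 and the acrylamide arrays in row 2, so treatment at night is confounded with array row, while in the morning the rows are mixed. For arrays, precision is limited by their number, 4 per group.

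Spots marked as uneven or as outliers among replicate spots were removed, and log2 of each spot's processed signal was taken. The log2 values of replicate spots of a probe were then averaged, which left 45 empty values among 30367 probes on 24 arrays. Each array's 75th percentile was subtracted, so a level of 0 stands for that percentile. A probe was kept when it was well above background on at least 3 of the 4 arrays of at least 1 group, which 23414 probes were. Probes were named by matching their accession to the reference gene names (18384 probes), then by symbol (2485) or synonym (528), and 8970 kept the name on the array. The 2 design annotations in the headers give different names to 3180 probes; probes were matched by identifier and the newer annotation was used. For each gene the probe with the highest mean was taken, giving 20272 genes tested, 14343 of them with a gene symbol. Other probes of a named gene are mentioned where they have the opposite sign.

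Group means were fitted to all 24 arrays in limma 3.58.1 under R 4.3.3 (with statmod 1.5.0 and, for reading files, the package data.table, version 1.17.8), with moderated variances and 18 residual degrees of freedom, and Benjamini-Hochberg adjusted p under 0.05 over all genes tested was the threshold. All tests were 2-sided, and every adjusted p is from limma or its list tests. The comparisons were acrylamide against control in each of the 3 strata (females at night, males at night, females in the morning), the mean of the 3 differences, the differences of the acrylamide effect by sex at night and by time in females, night against morning in control females and males against females in controls at night. A fold is given as "at least" where none of the 4 arrays of a group was well above background for the gene. It was then taken against the lowest well-above-background level of each array, or the level of the gene where that was higher. Errors are the model's standard error (SE) for a difference and the standard deviation (SD) for a group mean.

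Before the data were examined, the comparisons, the naming rule, 35 gene lists and the alternatives were fixed. The lists cover thyroid function, the clock, stress and metabolic responses, immune responses, and markers of tissues and cell types that border or enter the gland. Of these, 34 had at least 3 genes tested; of the 6 sex-linked genes listed, 0 were among the genes tested. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 34 lists of a comparison. Named genes per acrylamide comparison were, among genes with a symbol and no overlap between the 4 and 4 arrays, the 12 largest differences in each direction past the threshold, with free places going to unadjusted p under 0.01. Up to 10 in each direction were named for time and sex, up to 4 passing members or 2 others per list, and Tg, Slc5a5 and Tshr throughout. A part of these is printed, and 2 genes that the rule named are not reported here. Pituitary hormone genes and Kdm6a and Eif2s3 were chosen after their values were seen.

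The fit was tested on simulated data for 20232 genes with the spread of each stratum. Of 100 genes changed by 1 log2 unit, 44 were recovered for females at night, 63 for males at night and 59 for females in the morning; for 2 log2 units the numbers were 84, 89 and 90. False calls made up 6.57% of calls for females at night, 44.9% for males at night and 47.3% for females in the morning. The simulated spread differed between strata but was the same for the control and acrylamide arrays of a stratum. With a fit to only the arrays compared the shares were 5.41%, 6.19% and 3.57%, and with equal simulated spread in the fit to all arrays 8.33%, 7.35% and 4.96%. A count for males at night or females in the morning is therefore read beside the fit to its own arrays.

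Alternatives were quantile normalization, normexp background correction with an offset of 50, no filter, a filter on all 24 arrays, all probes, the deposited series matrix, only the arrays compared, slide or replicate number as a block, array weights, muscle and fat list means as covariates, and each array left out in turn. A pair of alternatives, leaving out females in the morning with acrylamide replicates 1 and 3 or those and 3 more arrays, was chosen after seeing the data.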

Results

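The data are 24 expression arrays of thyroid glands from rat pups, 4 for each of 6 groups: females at night, males at night and females in the morning, each with and without acrylamide in the drinking water at 3 mg per kg body weight per day. Acrylamide is a reactive small molecule that binds thiol groups. The labels ask which expression changes go with changes in plasma hormones at a low chronic dose. With 4 arrays per group their number limits precision. Between 71.5% and 82.3% of spots per array were well above background. The median SD over genes was 0.18 (control) and 0.23 (acrylamide) in females at night, 0.25 and 0.39 in males at night, and 0.25 and 0.45 in females in the morning (n = 4 each).

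In females at night no gene passed the threshold with acrylamide. Among the genes named by the rule, which did not pass, were Srxn1, a sulfiredoxin that reduces oxidised peroxiredoxins (0.70 log2, SE 0.25), Hsph1, a heat shock protein (0.75, SE 0.22), and Zyg11a (1.11, SE 0.34). Larger differences, given further on, did not pass either. On the negative side stood Gp5, a platelet glycoprotein (-1.41, SE 0.49), Ogn, a matrix proteoglycan (-0.94, SE 0.29), and Plk2, a p53 target kinase (-0.72, SE 0.23), each with adjusted p = 1 and n = 4 against 4. The thyroid genes had values near control: Tg, the hormone precursor, 0.06 (SE 1.04), Slc5a5, the iodide transporter, -0.09 (SE 1.18, its other probe has the opposite sign), and Tshr, the receptor for thyrotropin, 0.35 (SE 0.63). Each SE rests on a spread pooled over all groups, so it is not the spread among females at night. For Tg the pool includes acrylamide replicate 1 of females in the morning, at -1.189, far from the rest of its group. In females at night the mean of the thyroid follicular list had an SD of 0.066 (control) and 0.151 (acrylamide).

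Of the 34 lists, camera called 9 in this comparison. T cell and thymocyte markers were higher by a median of 1.27 (15 of 16 members positive, adjusted p = 3.09e-06), with Cd3e at 2.68 (SE 1.37) and Lck, a T cell kinase, at 1.41 (SE 0.85). Cell cycle genes were higher by 0.31 (38 of 39 positive, adjusted p = 6.92e-06), the unfolded protein response by 0.22 (adjusted p = 0.000873) and the antioxidant list by 0.18 (23 of 29 positive, adjusted p = 0.00876). Skeletal muscle markers were lower by a median of -1.42 in 28 of 28 members (adjusted p = 2.45e-18), with Myh1 at -1.41 (SE 0.68), fibroblast markers by -0.41 (1e-11), red cell markers by -0.49 (2.09e-05), macrophage markers by -0.27 (3.07e-05) and oxidative phosphorylation by -0.14 (0.000123). None of the 9 was called by camera in its other form: adjusted p = 0.508 with an estimated correlation for muscle, fibroblast, red cell and antioxidant lists, 0.565 for macrophages, 0.629 for the T cell and unfolded protein lists and 0.761 for the cell cycle and oxidative phosphorylation. That form called 0 lists in every comparison, also in night against morning, where 9132 genes passed. Here and below it therefore cannot show that a list did not change. The mean of the muscle list was 3.31, 1.45, 4.51 and 5.16 in the 4 acrylamide arrays against 4.65 to 5.38 in controls, so muscle content differed between arrays of the same group. The other 25 lists had adjusted p from 0.102 to 0.996, and in all 34 lists 0 genes passed adjusted over the list alone.

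The limma count was 0 genes, with 357 of 20272 (1.76%) at an unadjusted p under 0.05. These p-values rest on a spread pooled over all groups, while the arrays of females at night spread less (median SD 0.18 and 0.23). The share can therefore not be read against 5%. Shares of this kind in the other comparisons rest on the same pooled spread. The 4 and 4 arrays did not overlap for 1159 genes (5.72%, chance 2.86%). At night all control arrays lie in row 1 of their slide and all acrylamide arrays in row 2, in both sexes, so treatment cannot be told apart from array row.

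In males at night no gene passed either, but the values were larger. Prl, encoding the pituitary hormone prolactin, stood at 8.29 (SE 1.38, adjusted p = 0.0904), with Cga, the alpha subunit shared by pituitary glycoprotein hormones, at 4.98 (SE 1.09), Gh1, growth hormone, at 4.81 (SE 0.96) and Pomc, the precursor of corticotropin, at 3.98 (SE 0.80), all 4 acrylamide arrays lying above all 4 controls. Bhlhe40, a repressor in the clock, stood at -2.18 (SE 0.37, adjusted p = 0.0904), Cyp2e1, the enzyme that oxidises acrylamide to glycidamide, at -1.97 (SE 0.52) and Cd209f at -2.02 (SE 0.38). Also among the genes that did not pass were Gsta1, a glutathione transferase, 1.15 (SE 0.28), Srxn1 1.10 (SE 0.25), Txn1, thioredoxin, 0.75 (SE 0.19), and Ptgr1, a reductase of reactive carbonyls, 1.55 (SE 0.38). Tg (0.11, SE 1.04), Slc5a5 (0.72, SE 1.18, other probe of opposite sign) and Tshr (0.19, SE 0.63, other probe of opposite sign) did not pass. Their SEs again rest on the spread pooled over all groups. In males at night the mean of the thyroid follicular list had an SD of 0.07 (control) and 0.125 (acrylamide).

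**Figure D1:**
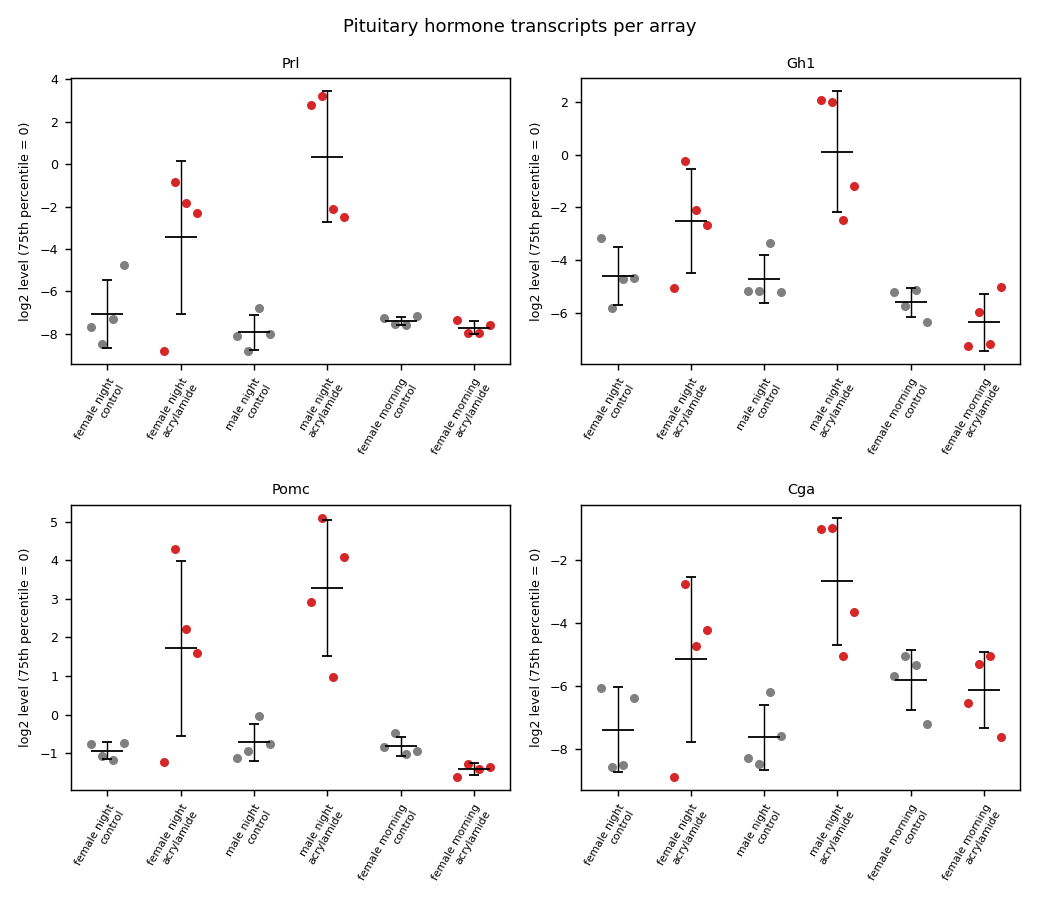
Log2 levels (75th percentile of the array = 0) of Prl, Gh1, Pomc and Cga in each of the 24 arrays by group; grey points are controls, red points acrylamide, horizontal bars the mean and error bars the SD of 4 arrays. In males at night Prl has a mean of 0.36 with acrylamide against -7.92 in controls, and in females in the morning it was well above background on 0 of 4 arrays in either group.

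The pituitary hormones were chosen after their values were seen. Fshb, the subunit of follicle stimulating hormone, stood at 0.42 (SE 0.32), and Lhb at 1.09 (SE 0.29), while Tshb, the thyrotropin subunit, was well above background on 2 of 4 acrylamide arrays and 0 of 4 controls. In females at night Prl was 3.61 (SE 1.38) and Pomc 2.65 (SE 0.80), with adjusted p = 1. In females in the morning Pomc was -0.59 (SE 0.80), and Prl was well above background on 0 of 4 arrays in either group. The mean of Prl, Gh1, Pomc and Cga differed by 5.51 in males at night, the arrays in which these genes were picked, so no p is given there. It differed by 2.64 in females at night (exact permutation p = 0.143) and by -0.49 in females in the morning (exact permutation p = 0.114), where Pomc was the 1 of the 4 genes well above background in both groups. Among night controls Prl was well above background on 1 of 4 arrays in each sex, and Cga on 1 of 4 in males and 2 of 4 in females. The sizes at night for these genes and for the mean are thus taken partly against levels near background.

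Camera called 9 lists in males at night. Higher were the antioxidant list (median 0.21, 19 of 29 positive; 3 genes higher adjusted over the list alone, adjusted p = 0.00165), the unfolded protein response (0.30, adjusted p = 0.00109), with the chaperone Hyou1 at 1.02 (SE 0.30), and the cell cycle (0.33, adjusted p = 0.00109). Lower were skeletal muscle (median -1.94, 28 of 28 negative, adjusted p = 8.28e-12), fibroblasts (-0.49; 0.000157), inflammatory cytokines (-0.57; 3 of 21 lower adjusted over the list alone; 0.000227), macrophages (-0.53; 0.000448), oxidative phosphorylation (-0.25; 0.000448) and the core clock (-0.37; 6 of 22 lower adjusted over the list alone; 0.00219). In the inflammatory list Selp, the endothelial adhesion molecule P-selectin, stood at -1.32 (SE 0.29) and Ccl2, a monocyte attractant, at -1.08 (SE 0.33); in the clock list Dbp stood at -0.67 (SE 0.20). With an estimated correlation none was called: adjusted p = 0.484 for the antioxidant and inflammatory lists, 0.719 for the clock, unfolded protein, muscle and macrophage lists and 0.822 for the others. The remaining 25 lists had adjusted p from 0.0929 to 0.923, among them acrylamide and xenobiotic metabolism (median -0.07, 13 of 28 positive, adjusted p = 0.854). The muscle list mean was 5.56, -0.46, 4.72 and 3.05 in the acrylamide arrays against 4.82 to 6.09 in controls, and that of parathyroid markers was -1.62 in acrylamide replicate 4 against 2.17 to 2.79 in controls.

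The limma count was 0, with 2697 genes (13.3%) at an unadjusted p under 0.05. That share rests on the pooled spread, while the acrylamide arrays of males at night had a median SD of 0.39, so it cannot be read against chance. Without acrylamide replicate 1 the count was 21 and without replicate 3 it was 7. In acrylamide replicate 4 the Y-linked Ube1y1 stood at -7.09, against -4.02 to -3.79 in the other 3 and -8.90 to -8.52 in female controls, and without it the count was 0. The arrays did not overlap for 911 genes (4.49%, chance 2.86%).

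In females in the morning 451 genes passed with acrylamide, 96 higher and 355 lower. In a fit to the arrays of this stratum alone no gene passed, and in the simulation 47.3% of calls for this comparison were false. The single genes below are read with that limit. Cxcl13, a B cell chemokine (probe A_64_P013437, chromosome 14, 15127379 to 15127438), fell by 2.08 (SE 0.32, adjusted p = 0.0183), from -0.23 ± 0.11 to -2.32 ± 0.73 (SD, n = 4 each). Irs4, an insulin receptor substrate (-2.01, SE 0.46), Cfb, complement factor B (-1.82, SE 0.43), and Inhbb, the inhibin beta B subunit (-1.82, SE 0.45), also fell. Ass1, argininosuccinate synthase of the urea cycle (probe A_44_P447373, chromosome 3, 10620727 to 10622079), rose by 2.22 (SE 0.40, adjusted p = 0.0184), and Fhl2 (2.13, SE 0.48), Wif1, a Wnt inhibitor (1.27, SE 0.32), and Dhps, an enzyme of hypusine synthesis (1.26, SE 0.23), rose too. For Ass1, acrylamide replicate 4 (-4.775) and control replicate 1 (-4.895) stood apart from the rest of their groups and lay close to each other. Of the glutathione transferases, Gstm1 rose (0.97, SE 0.21) while Gsta4 (-1.35, SE 0.32) and Gstt2 (-0.79, SE 0.21) fell.

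Cell division genes were higher: 4 of 39 cell cycle genes rose, Top2a, a topoisomerase (1.70, SE 0.38), Cenpf, a kinetochore protein (1.65, SE 0.38), and the cyclins Ccnb2 (1.45, SE 0.36) and Ccnb1 (1.40, SE 0.37), and 15 were higher adjusted over the list alone. Outside the list Cenpa, the centromeric histone, rose by 1.55 (SE 0.40, at least 2.79-fold higher) and Kif2c, a mitotic kinesin, by 1.44 (SE 0.37). Camera called the list up (median 0.68, adjusted p = 4.83e-10, adjusted p = 0.672 with an estimated correlation). The list mean was -0.22 in acrylamide replicate 2 and -2.11 in the lowest acrylamide array, against -2.48 to -2.02 in controls, and in replicate 2 the mean of the T cell and thymocyte markers was 0.78 against -3.80 to -2.33 in controls.

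Thyroid follicular genes were lower: of 25, Foxe1, a transcription factor of thyroid development (-1.12, SE 0.25), and Duox2, which makes hydrogen peroxide for iodination (-0.80, SE 0.19, arrays overlap), fell, and 11 were lower adjusted over the list alone. Camera called the list down (median -1.12, adjusted p = 1.74e-06, adjusted p = 0.672 with an estimated correlation). Tg (-2.27, SE 1.04, adjusted p = 0.196), Slc5a5 (-2.40, SE 1.18, 0.224; other probe of opposite sign) and Tshr (-1.69, SE 0.63, 0.123) did not pass. The list mean was -3.17 in acrylamide replicate 1 and 0.15 to 0.71 in the other 3, against 0.63 to 1.02 in controls. Oesophageal epithelium markers, from an organ beside the gland, had a mean of 0.79, -1.51, 1.47 and -3.14 in the acrylamide arrays against -2.97 to -1.91 in controls, and Krt13, a keratin of that epithelium, rose by 4.80 (SE 1.15, adjusted p = 0.0378; arrays overlap), while Dsc3, a desmosomal cadherin, fell (-1.42, SE 0.33).

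**Figure D2:**
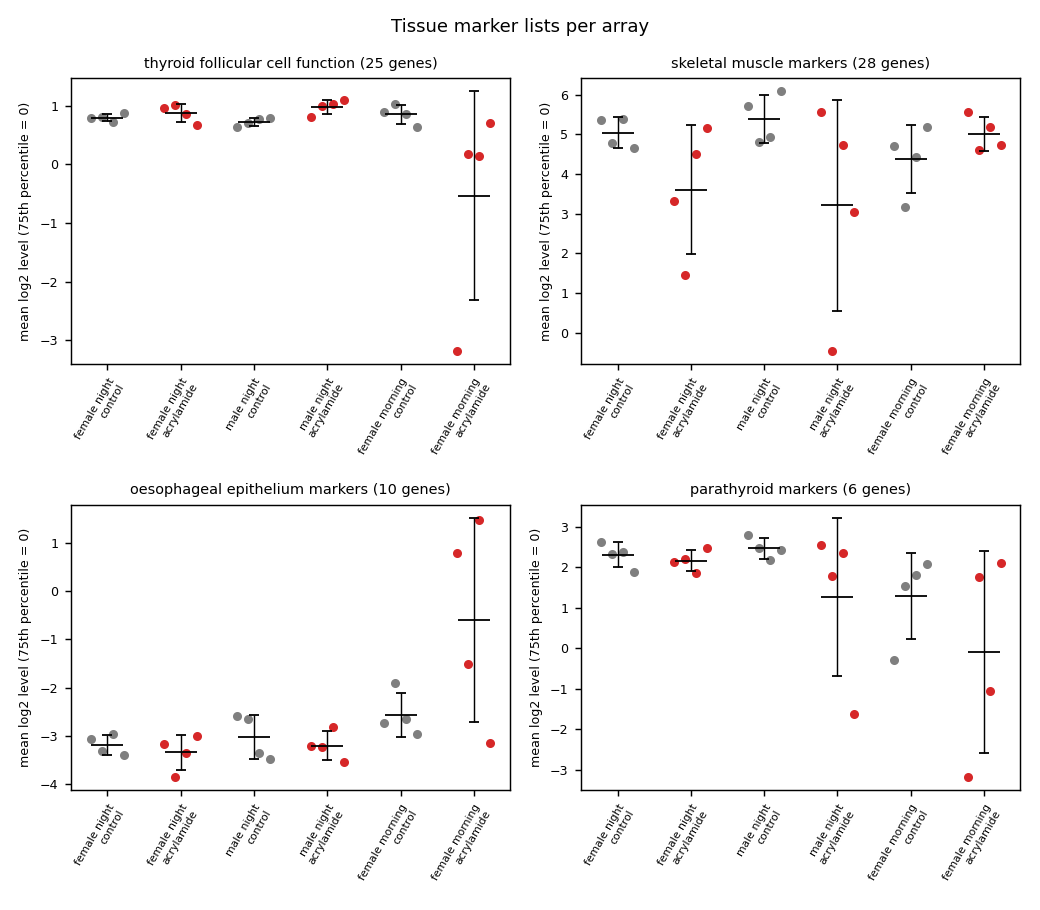
Mean log2 level (75th percentile of the array = 0) of the genes of 4 tissue marker lists in each of the 24 arrays by group; grey points are controls, red points acrylamide, horizontal bars the mean and error bars the SD of 4 arrays. The thyroid list reaches -3.17 in 1 acrylamide array of females in the morning, and the muscle list -0.46 in 1 acrylamide array of males at night.

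Camera also called oesophageal markers (median 2.64, adjusted p = 0.00067), cartilage (1.34; 8.69e-05), oxidative phosphorylation (0.19; 0.000593), skeletal muscle (0.69; 0.0284), heat shock proteins (0.24; 0.00605) and the glucocorticoid response (0.43; 0.00242) up, and the unfolded protein response (-0.41; 0.00197) and C cell markers (-1.02; 0.0279) down. The acrylamide arrays spread widely in the lists called down. The C cell mean ran from -4.21 to -0.53 against -1.02 to -0.20 in controls, and the unfolded protein mean from -0.29 to 0.84 against 0.72 to 1.09. Sgk1, a glucocorticoid-induced kinase, rose (0.63, SE 0.15), Mt2A, a metallothionein, fell (-1.49, SE 0.37), and so did Atf6, a sensor of unfolded proteins (-0.72, SE 0.19). Adjusted over the list alone, 9 of 31 unfolded protein genes were lower, 6 of 10 oesophageal genes higher and 1 lower, 4 of 16 cartilage genes higher, and 4 of 20 glucocorticoid genes higher and 2 lower. None of these was called with an estimated correlation: adjusted p = 0.445 with an estimated correlation for heat shock and glucocorticoid lists, 0.672 for oesophageal, cartilage and unfolded protein lists and 0.804 for the rest. The remaining 24 lists had adjusted p from 0.0883 to 0.917; among their members Mx2, an interferon-induced GTPase, fell (-0.55, SE 0.10), Kdr, a receptor of vascular endothelial growth factor, fell (-0.96, SE 0.20) and Hlf, a clock output factor, fell (-1.53, SE 0.34).

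The count moved with single arrays: without control replicates 1, 2, 3 and 4 it was 60, 0, 19 and 223, and without acrylamide replicates 1, 2, 3 and 4 it was 33, 1047, 1929 and 1701. A limma fit to these 8 arrays alone called 0 genes, and with slide as a term 90 were called. With a control left out the median size of the 451 differences was 0.962 to 1.03 times that on all arrays, and the median error 1.1 to 1.11 times. The arrays did not overlap for 1668 genes (8.23%, chance 2.86%). The 10 spike-in sequences differed by -0.68 to -0.23 with acrylamide in this stratum, and by 0.11 to 0.45 in males at night. Whether this bears on the split into genes higher and lower was not tested.

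The mean of the 3 differences asks for changes common to sexes and times. Cxcl13 fell by 1.21 (SE 0.18, adjusted p = 0.0318), with -0.88 (SE 0.32) in females at night, -0.68 (SE 0.32) in males at night and -2.08 in females in the morning. It was the 1 gene called in limma, with 1355 genes (6.68%) at an unadjusted p under 0.05, and Tg stood at -0.70 (SE 0.60). Of 14 lists called, 7 were higher, with the cell cycle first (median 0.42; 16 of 39 higher adjusted over the list alone, adjusted p = 5.78e-23), and 7 lower, with skeletal muscle first (median -0.97, adjusted p = 9.96e-11). The muscle call is no common change, since its median was -1.42 and -1.94 at night and 0.69 in females in the morning. The adjusted p = 0.353 with an estimated correlation for the former and 0.552 for the latter, and none of the 14 was called. The other 20 lists had adjusted p from 0.0935 to 0.898. The call was lost with the deposited series matrix (0 genes) and with muscle and fat list means as covariates (0 genes). The count was 29 without acrylamide replicate 4 of females in the morning, and 17 or 63 genes were called without the arrays that stand apart in their tissue markers.

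Whether the acrylamide effect differs by sex at night was tested directly. No gene passed in limma, with 422 genes (2.08%) at an unadjusted p under 0.05. Camera called 3 lists. Red cell markers had an effect higher in males by a median of 0.76 (adjusted p = 3.58e-05), interferon response genes by 0.07 (0.0492) and inflammatory cytokines by -0.51 (0.00284). The adjusted p = 0.848 with an estimated correlation for red cell and inflammatory lists and 0.954 for interferon, so none was called. The other 31 lists had adjusted p from 0.0837 to 0.98.

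For the difference by time in females limma called 0 genes, with 3291 genes (16.2%) at an unadjusted p under 0.05. Without acrylamide replicate 4 of females in the morning the count was 380, and with array weights 78. Camera called 15 lists, 12 with a higher effect in the morning, among them skeletal muscle (median 2.25, 28 of 28 positive, adjusted p = 4.79e-08) and oxidative phosphorylation (0.35; 7.13e-06), and 3 lower, among them thyroid follicular genes (-1.30, 23 of 25 negative; 2.06e-05). The adjusted p = 0.57 with an estimated correlation for these lists, and none of the 15 was called. The other 19 lists had adjusted p from 0.114 to 0.996, and the median over all genes was -0.12. Across genes, which are not independent replicates, the acrylamide effects correlated at 0.47 between females and males at night, -0.24 between females at night and in the morning, and -0.41 between males at night and females in the morning. Array row is shared by both night comparisons and cannot be told apart from treatment in the first. With muscle and fat list means as covariates the second became 0.04 and the third -0.07.

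Night against morning in control females asks what differs between the 2 collection times without acrylamide. Of the 22 clock genes, those higher at night were Tef (2.97, SE 0.24), Dbp (2.96, SE 0.20, adjusted p = 9.48e-11), Per2 (1.95, SE 0.23), Nr1d2 (1.81, SE 0.37), Nr1d1 (1.69, SE 0.52), Wee1, a kinase at the entry to mitosis (1.60, SE 0.16), Ciart (1.51, SE 0.61, at least 1.93-fold higher) and Csnk1d (0.59, SE 0.11, other probe of opposite sign). Bmal1, the activator of the clock (-2.63, SE 0.26, adjusted p = 3.38e-08), Per1 (-1.54, SE 0.40), Npas2, a paralogue of Clock (-1.18, SE 0.26), Usp2 (-1.02, SE 0.27) and Per3 (-0.66, SE 0.23, 2 other probes of opposite sign) were lower. These are 8 higher and 5 lower, 8 and 6 adjusted over the list alone, while camera did not call the list (adjusted p = 0.061); Ciart became -0.72 with normexp background correction. Clock (-0.25, SE 0.23), Cry1 (0.03, SE 0.22), Cry2 (-0.62, SE 0.26), Nfil3 (-0.02, SE 0.41), Rora (-0.50, SE 0.26), Bhlhe40 (0.20, SE 0.37), Bhlhe41 (1.14, SE 0.55), Csnk1e (-0.02, SE 0.35) and Hlf (0.46, SE 0.34, -0.63 with normexp) did not pass.

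**Figure D3:**
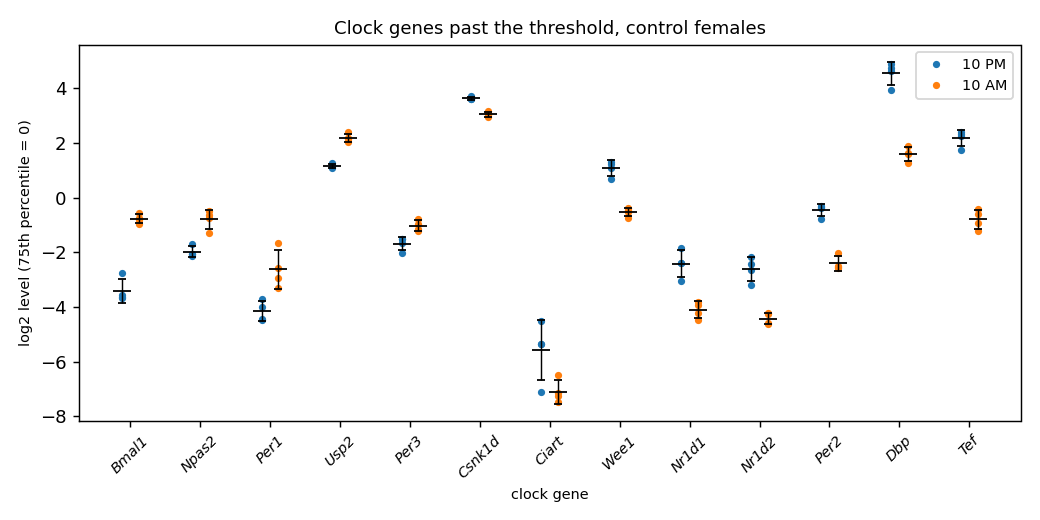
Log2 levels (75th percentile of the array = 0) of the 13 clock genes past the threshold in control females, at 10 PM (blue) and 10 AM (orange); points are arrays, horizontal bars the mean and error bars the SD of 4 arrays. Dbp has a mean of 4.55 at night against 1.59 in the morning, and Bmal1 -3.41 against -0.77; Ciart, at -5.59 against -7.10, turns to -0.72 for its difference with normexp background correction.

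In total 9132 genes differed, 2686 higher and 6446 lower at night, around a median over all genes of -0.15; 11200 (55.2%, chance 2.86%) did not overlap. The split turned to 5992 higher and 4735 lower with quantile normalization and 6399 and 4736 with the deposited series matrix. The largest were Id3, an inhibitor of DNA binding (-6.68, SE 0.36), Ergic2 (-6.43, SE 0.31), Oxnad1 (-6.15, SE 0.24, at least 38.8-fold lower) and Slc45a4 (-5.69, SE 0.24, at least 24.8-fold lower). Higher at night was Fmo2, a monooxygenase (2.95, SE 0.21), among others. Also lower at night were Slc26a4, the apical anion transporter of the thyroid cell (-3.32, SE 0.27, at least 4.92-fold lower), Foxe1 (-1.48, SE 0.25) and Th, tyrosine hydroxylase (-2.40, SE 0.22). Camera called 0 lists (adjusted p from 0.0597 to 0.919) and fry 4, namely dopamine and prolactin signalling (down, adjusted p = 0.00387), B cell markers (down, 0.0311), the clock (up, 0.0256) and xenobiotic metabolism (up, 0.0167), in which Cyp2e1 was higher at night by 1.85 (SE 0.52). Collection time cannot be told apart from slide and scan session in these arrays. The 7 spike-in sequences of lowest level at night differed by -0.94 to 0.29, and the other 3 were flat at 6.60 to 6.61 in the morning. The highest processed signal was 77183 to 87241 on the morning arrays, against 7.26e+05 to 8.79e+05 on the night arrays. Levels near that ceiling are limited in the morning, and differences of the brightest genes by time carry this limit.

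Males against females, in controls at night, lie on 2 slides, so sex cannot be told apart from slide. The comparison gave 2 genes: Ube1y1, of the Y chromosome, was 4.43 higher in males (SE 0.61, adjusted p = 0.00812; at least 9.91-fold), and the probe A_64_P030407, which has no gene symbol, was lower by -4.52 (SE 0.66, adjusted p = 0.0104; at least 14.3-fold). Kdm6a (-1.002, SE 0.21, adjusted p = 0.413) and Eif2s3 (-0.62, SE 0.15, adjusted p = 1), both X-linked, did not pass and were chosen after their values were seen. Cell cycle genes were higher in males by a median of 0.53 (37 of 39 positive, adjusted p = 3.57e-17) and oxidative phosphorylation by 0.29 (38 of 38; 3.96e-17), interferon response genes lower by -0.15 (0.00091) and macrophage markers by -0.16 (0.0152). None was called with an estimated correlation: adjusted p = 0.969 with an estimated correlation for the former pair and 0.998 for the latter. In limma 330 genes (1.63%) had an unadjusted p under 0.05, 750 (3.7%, chance 2.86%) did not overlap, and leaving out 1 array gave 0 to 3 genes.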

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

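Of the tests below, those of the mean of the unseen pituitary markers, of acrylamide at either collection time, of a slide shift as the whole cause, of male RNA and of a swap were chosen after the result was seen.

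Pituitary hormone transcripts (Prl, Gh1, Pomc and Cga) were picked for their large values in the acrylamide arrays of males at night, where their mean differed by 5.51, and in females at night by 2.64 (95% exact permutation interval -1.84 to 6.09). In females in the morning it differed by -0.49 and the interval ended at 0.29, but no more than 1 of the 4 genes was well above background in both groups there, so acrylamide acting at either collection time cannot be decided. Pituitary RNA or tissue in the samples is a candidate explanation that the data do not decide. On 23 pituitary markers not looked at before, camera gave p = 0.746 in males at night, with 11 positive, and their mean differed by -0.16 (exact permutation p = 0.629), while 12 of the 23 were already well above background in night controls. An effect of acrylamide at night only or in males only, array row and handling at collection stay open, untested.

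In females in the morning the 451 calls stood beside acrylamide arrays of differing tissue content, so other tissue in replicate 1 or the slide may have contributed. Without that array 33 genes were called and with slide as a term 90, both below the bound of 451 divided by 1.5 that was written beforehand. Leaving out control replicate 2 (0 genes) or 3 (19 genes) lowered the count as far, and a criterion on the size of the differences was added once the counts were known, so for neither can it be told. The median size of the 451 differences was 0.877 with a median error of 0.201 on all arrays, 0.701 and 0.184 without replicate 1, and 0.825 and 0.203 with the slide term. A slide shift as the whole cause is argued against by the size ratio of 0.934, while other tissue, an effect of acrylamide and the slide as a part stay open.

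Sex-dependent transcripts set control replicate 4 of females in the morning apart, with Kdm6a at -3.273 and Eif2s3 at 0.821. On the 5 genes that best separated the sexes in night controls its median position between the other female arrays (0) and a full male shift (1) was 0.597. Kdm6a prompted the test, and without it the median was 0.39, below the 0.5 asked for, so male RNA in that array is a candidate explanation that cannot be decided. Of the 5 genes, Ube1y1 (position 0.664) and A_64_P030407 (0.597) had passed the threshold between the sexes. LOC680578 (0.083), Ubn1 (0.183) and Kdm6a (0.97) had not, with limma adjusted p of 0.227, 0.413 and 0.413. Ube1y1 stood at -4.968 in this array, against a mean of -7.909 in the other arrays of females in the morning. Over 13 clock genes its median position between morning (0) and night (1) was -0.017. This cannot decide on a swap with a male night array analysed here. Time cannot be told apart from slide and scan session, and the 13 genes were called with this array among the morning controls. Males in the morning were not analysed here, so a sample from that group stays open, and no biological explanation was tested.

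An array stood far from the other 3 of its group in 12 of 210 list means and 14 of 232 groups for single genes, and about 1 in 20 groups does so by chance. The arrays named most often were acrylamide replicate 1 and control replicate 4 of females in the morning, 5 times each. These counts include Kdm6a, Eif2s3 and the pituitary hormones, which were chosen after their values were seen. Their part in the counts, mostly in control replicate 4, cannot be set against the chance rate. In acrylamide replicate 1 these were the thyroid follicular list (-3.173), the B cell list (-4.755), Tg (-1.189), Tmem252 (-2.688) and Cfb (-0.031). In control replicate 4 they were, besides the 2 genes above, cartilage markers (-1.089), the pituitary hormone mean (-5.408) and Zmym3 (-6.108). Other arrays of females in the morning were acrylamide replicate 2 in the cell cycle (-0.215) and interferon (-0.797) lists, acrylamide replicate 4 in Ass1 (-4.775), and control replicate 1 in Ass1 (-4.895) and Gcm2 (-7.297). In females at night control replicate 3 stood apart in the antioxidant list (1.32) and Kdm6a (-2.506), acrylamide replicate 3 in airway epithelium (-4.599) and acrylamide replicate 1 in Eva1a (-5.036). In males at night control replicate 4 did in the thyroid hormone response (-0.367) and cartilage (-4.287), control replicate 1 in neutrophils and mast cells (-3.641) and fibroblasts (1.069), control replicate 3 in Gh1 (-3.339) and A_64_P030407 (-8.766), and acrylamide replicate 4 in Clec1b (-6.32).

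The acrylamide effect differed between males and females at night by camera in the lists for red cells (median 0.758), inflammatory cytokines (-0.505) and interferon (0.068). None of these was called with an estimated correlation (adjusted p of 0.848 to 0.954). Between morning and night in females 15 lists differed, with adjusted p of 0.57 to 0.634 with an estimated correlation. Higher in the morning were skeletal muscle (2.251), oesophagus (2.217), cartilage (1.468), fibroblasts (0.639), Schwann cells (0.504), the glucocorticoid response (0.452), macrophages (0.437), kinesins and tubulins (0.415), the cell cycle (0.38), oxidative phosphorylation (0.35), heat shock proteins (0.253) and smooth muscle (0.194). Lower were thyroid follicular genes (-1.304), C cells (-1.211) and the unfolded protein response (-0.718).

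Other splits of the same arrays were counted for each comparison, the real split included. Chance could be excluded for night against morning, where 1 of 35 splits called as many genes (real 9132, highest other 1), and for males against females (1 of 35, real 2, highest other 0), which leaves slide, and for the former also scan session, as open as before. It could not be excluded for acrylamide in females in the morning (2 of 35, real 451, highest other 1208). A real count of 0 is matched by every split, so the splits decide nothing for acrylamide in females at night (35 of 35, real 0, highest other 0) and males at night (35 of 35, real 0, highest other 2110). The 2110 and 1208 genes point to a structure of the samples, though what it is was not tested. Unequal spread between strata is not excluded. It gave 124 and 134 false calls in the simulations for males at night and females in the morning. Those simulations also held changed genes and drew each gene independently, so their counts are not on the same footing as the splits. The 1208 came from exchanging control replicate 4 and acrylamide replicate 4. For list calls 20 of 35 splits gave as many in females at night (real 9, highest other 14), 9 of 35 in males at night (real 9, highest other 11) and 23 of 35 in females in the morning (real 10, highest other 21), so chance could not be excluded. Of 100 random re-labellings within strata, 7 gave as many genes for the mean of the strata (real 1, highest other 1210), so chance could not be excluded, and the 1210 genes are open to the same readings. For the difference by sex 100 did (real 0, highest other 0) and for that by time 100 (real 0, highest other 7), which again decides nothing. For the correlation of effects across genes, chance could be excluded between females and males at night (1 of 100, real 0.4696, highest other 0.4455). Between males at night and females in the morning the count was 3 of 100 (real -0.4059), and the highest other, 0.4203, lay further from 0. The counts were not adjusted for the number of tests, so chance is not firmly excluded there. Re-labelling does not exclude array row, which coincides with treatment at night, nor uneven tissue content of the arrays. The correlation between males at night and females in the morning shrank with muscle and fat list means as covariates, as given below. Chance could not be excluded between females at night and in the morning (14 of 100, real -0.2411, highest other 0.3903).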

How the results depend on the processing

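The alternatives that left out 2 or 5 arrays were chosen after seeing the data, and the others beforehand. The cause was not tested for any change below, except that no filter tested 26246 genes and the filter on all arrays 15631, against 20272. Between 71.5% and 82.3% of spots per array were well above background, and the number of arrays, 4 per group, limits precision. A named gene's result counted as kept if it passed in both fits in the same direction, or passed in neither. Where it passed in neither, direction was not compared. Of the named genes' 515 results, 491 were kept with quantile normalization, 466 with normexp, 487 with no filter, 508 with all probes and 449 with the series matrix. With only the arrays compared 462 were kept, 475 with slide, 470 with the replicate block, 471 with array weights and 499 with covariates. With 2 and 5 arrays left out 477 and 478 were kept. With the filter on all arrays 406 of 410 were, and leaving out single arrays 3932 of 4232.

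For acrylamide in females in the morning (451 genes) the count was 965 with quantile normalization, 112 with no filter, 12 with the series matrix, 0 with only the arrays compared, 90 with slide, 0 with the replicate block, 120 with array weights and 168 with 2 arrays left out. List calls (10) were 5 with 2 arrays left out. In males at night (0) the count was 3 with normexp, 2 with the series matrix, 1 with the replicate block, 2 with array weights and 15 with 2 arrays left out. For the mean of the strata (1) it was 3 with normexp, 0 with the series matrix, 2 with array weights, 0 with covariates, and 17 and 63 with 2 and 5 arrays left out. For the difference by time (0) it was 78 with array weights and 3 with 5 arrays left out. Night against morning (9132) gave 14090 with no filter. Males against females (2) gave 1 with quantile normalization, 0 with normexp, 0 with the filter on all arrays, 36 with array weights and 5 with 5 arrays left out.

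The correlation between females and males at night (0.4696) was 0.574 with normexp, 0.3793 with no filter, 0.5644 with the filter on all arrays, 0.396 with array weights, 0.3626 with covariates and 0.3173 with 5 arrays left out. Between females at night and in the morning (-0.2411) it was -0.3346, -0.14 and -0.3285 under the first 3 of these. It reversed to 0.0407 with covariates and 0.0224 with 2 arrays left out, and was -0.0469 with 5 left out. Between males at night and females in the morning (-0.4059) it was -0.4871, -0.3541 and -0.5095 under the same 3, -0.3495 with slide, -0.3537 with array weights, -0.0681 with covariates, and -0.2599 and -0.057 with 2 and 5 arrays left out.

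Among named genes that passed in the main fit or in the alternative, Mx2 for night against morning reversed to 0.056 with quantile normalization and 0.076 with the series matrix. With normexp Rapgef4 reversed to -0.01 for acrylamide in females in the morning. For night against morning normexp reversed Txndc16 (-0.153), Apcdd1 (-0.338), Ripk4 (-0.394), Ifit3 (-0.508), Kif3a (-0.094), Syp (-0.021), Tekt2 (-0.308), Tekt1 (-0.729), Hlf (-0.626) and Ciart (-0.72).

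Leaving out single arrays gave 0 to 0 genes in females at night, 0 to 21 in males at night (21 without acrylamide replicate 1, 7 without replicate 3), 0 to 1929 in females in the morning, 0 to 29 for the mean, 0 to 0 for the difference by sex, 0 to 380 for that by time (380 without acrylamide replicate 4 of females in the morning), 7993 to 8539 for night against morning and 0 to 3 for males against females. List calls were 9 to 12, 9 to 12 and 8 to 15 in the 3 strata. The 3 correlations ranged from 0.3663 to 0.5117, from -0.3102 to -0.1268 and from -0.4485 to -0.3132.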

Other observations

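Every value here was looked at after the results were seen. On the 5 genes that best separated the sexes, acrylamide replicate 4 of males at night had a median position of 0.37 between female night controls (0) and a full male shift (1), with Kdm6a at 0.011, Ubn1 at 0.028, Ube1y1 at 0.37, LOC680578 at 0.48 and A_64_P030407 at 0.83. Of these genes only Ube1y1 and A_64_P030407 had passed the threshold between the sexes. The consensus correlation of arrays on the same slide was 0.0588. Median processed signal was 210 to 400.5 on the night arrays and 81.4 to 188 on the morning arrays.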
